A study of Drosophila melanogaster with 2 samples.

How the data were processed

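Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out with an antibody to GFP on whole Drosophila melanogaster embryos aged 0 to 24 h from a line expressing tna fused to eGFP. Per the labels, chromatin was sheared by sonication to a size range of 200 to 800 bp, and the 2 samples are biological replicates 1 and 2, which form 1 group. A control library was not analysed here, so no background measured in untagged embryos stands beside any value.

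The authors deposited peak lists on the dm6 build. Per the file headers and notes, 1 thresholded and 1 ranked list derive from each replicate's own alignment, and 2 thresholded and 2 ranked lists derive from both replicates. The irreproducible discovery rate (IDR) scores how repeatably a peak ranks in a pair of lists. The aligner, the peak caller and their versions are not given in the sources used here. The deposited signal of a peak is the caller's own value, never negative, and no step that would put different lists on a common scale is stated, so signals were ranked and compared only within a list, and each replicate's value is printed by itself. The deposited −log10 values are of the q-value in the thresholded lists and of the global IDR in the ranked lists. Read counts are not part of these lists, so the depth of each library is unknown and no interval that needs it was computed.

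Each thresholded list was matched to its ranked list by coordinates, summit and signal. All 2580 conservative peaks were found in a ranked list that pairs both replicates, at a −log10 IDR of at least 2.00, which is an IDR of at most 0.01. This list, the peaks reproducible between replicates, served all main results. Of the 2580 peaks, 1674 had a q-value of at most 0.05 in the deposited column. A further 172 of the 2580 peaks shared both of their replicate peaks with a stronger listed peak, leaving 2408 distinct pairs.

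The reference was the RefSeq sequence of the dm6 assembly with the Ensembl annotation of release 115, in the same coordinates. Peaks on the 7 assembled arms (2L, 2R, 3L, 3R, 4, X and Y) were used. Transposable elements and pseudogenes were left out of the transcription start sites (TSSs). A peak was TSS-proximal when its summit lay within 500 bp of a TSS, and a gene was called bound when a summit lay within 500 bp of any of its TSSs. Background for gene lists was all other protein-coding genes of the 13968 on these arms.

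The TSS-proximal share and the overlap of replicates were set against 1000 circular shifts of the peaks along each arm. Arms were tested by exact binomial tests, gene lists by two-sided Fisher's exact tests and motifs by exact McNemar tests, each adjusted by the Benjamini-Hochberg method within its family of 7 arms, 19 lists or 18 motifs. Motif matches on either strand within 100 bp of a summit were compared with a window of equal width 1000 bp away, on a side drawn at random. Motif ratios and all odds ratios were computed after adding a small constant to every count, which keeps them finite at counts of 0. They therefore differ from ratios of the printed counts. Median signals were compared by a permutation test with 100000 resamples. The threshold was an adjusted p of 0.05. Intervals are exact (Clopper-Pearson) at 95% for shares, and the limit for Y, with 0 peaks, is 3 counts of the total. Those of odds ratios are Wald intervals on the log scale at 95%. As peaks or genes are not independent replicates, p-values describe peaks and genes, not embryos. The replicates are labelled as biological, and with 2 of them no test across samples was made.

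The gene lists, the motifs and the tests of the main results were fixed before the data were examined, as was the rule for named genes. That rule took tna, the 25 conservative peaks with the highest signal, up to 4 bound members with the highest signal of each list past the threshold and up to 2 of each other list, and the 10 genes with the most peaks among those with at least 3 in the body or within 500 bp, with ties settled by summed signal. Each of the 25 peaks was named by the nearest protein-coding TSS within 500 bp, otherwise by the gene holding its summit. List members were counted by a summit within 500 bp of their own start even where another gene's start was nearer, and the text then names that gene. Some list symbols without a match in the annotation are not reported here.

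The tests were tried on simulated data before use. With 2580 simulated peaks placed around starts of the 13968 genes, a planted list passed and no other list did, and a planted motif passed. Of 200 random lists of 20 genes, 11 had an unadjusted Fisher p under 0.05 in the conservative list. Alternatives covered the other list from both replicates, each replicate alone, TSS windows of 250 and 1000 bp, motif windows reaching 50 and 200 bp, shuffled and promoter-matched control windows, other overlap rules and other thresholds. Alternatives at an IDR of 0.05 or 0.001, at a q-value of 0.05, with 1 peak per replicate pair, and with left-out ranked peaks added back were chosen after seeing the data. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.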

Results

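Binding of the tagged protein of tna (tonalli) was profiled in whole embryos by ChIP-seq against GFP. The gene encodes an SP-RING protein related to SUMO ligases, known from genetic interactions with the Brahma chromatin-remodelling complex. Embryos aged 0 to 24 h hold all embryonic stages and tissues together. There were 2 biological replicates in 1 group, so the questions are where the peaks lie, how far the replicates share them, and which genes and sequences they mark.

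The replicate 1 list held 2217 peaks, 2214 of them on the assembled arms, and the replicate 2 list held 2669. The conservative list held 2580 peaks with a median width of 410 bp, covering 841 kb, and the other list made from both replicates held 3500, of which 2349 were identical to conservative peaks. The authors' signal per conservative peak had a median of 169 and ranged from 2.08 to 1797. The depth of the libraries is unknown.

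The replicates shared most of the replicate 1 peaks. Of the replicate 1 peaks, 1529 (69.1%) overlapped a replicate 2 peak by at least 1 bp, against a mean of 1.18% and a maximum of 2.17% after circular shifts. Of the replicate 2 peaks, 1522 of 2669 overlapped a replicate 1 peak. Shared peaks were the stronger ones, with a median signal of 119 against 70.8 for unshared peaks in replicate 1 and 113 against 75.8 in replicate 2. Promoters of 1697 protein-coding genes had a peak in both single lists, 600 in replicate 1 alone and 769 in replicate 2 alone. The permutation p of the overlap was 0.001, one-sided and the smallest that 1000 shifts can give. Across the 2580 conservative peaks the log2 signals of the paired replicate peaks had a Pearson r of 0.732 (95% interval 0.714 to 0.749) and a Spearman rho of 0.628, as a description across peaks that were themselves selected for reproducibility. Across all 115157 ranked pairs r was 0.319.

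Peaks of the tagged protein sat at transcription start sites. Of the 2580 summits, 2217 (85.9%) lay within 500 bp of a TSS, 6.39 times the mean of 13.5% ± 0.874 (SD over 1000 shifts). Protein-coding starts accounted for 2072 of these peaks, and 145 lay only near starts of noncoding genes. Around protein-coding starts the median summit lay 25 bp upstream (median position -25, quartiles -60 and 19), and 1600 of the 2072 summits (77.2%) were within 100 bp of the start. Away from starts, 195 summits (7.56%) lay in introns, 96 (3.72%) between genes, 39 (1.51%) in coding exons, 22 (0.853%) in 3′ UTRs and 5 (0.194%) in 5′ UTRs. The two-sided permutation p of the TSS share was 0.002, the smallest these shifts can give, and the share was 86.5% in the replicate 1 list and 85.5% in the replicate 2 list.

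**Figure D1:**
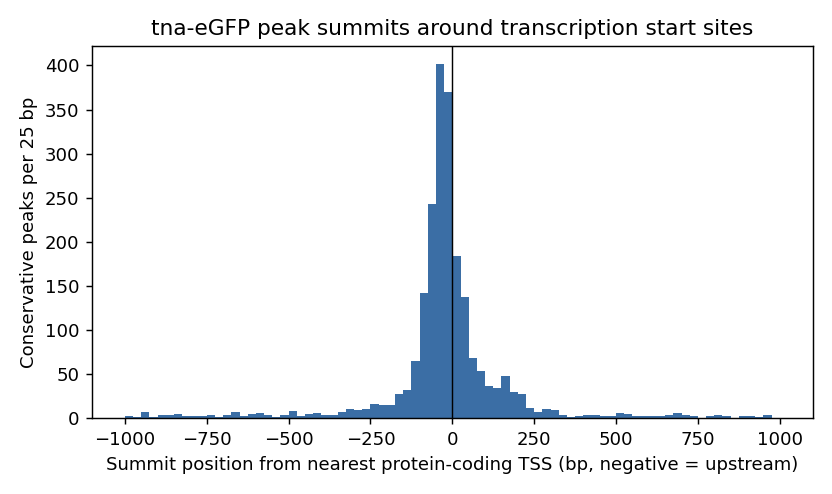
Histogram of conservative peak summits by distance in bp from the nearest protein-coding TSS, in bins of 25 bp, with negative values upstream. The summits pile up just upstream of the start, with a median at -25 bp among those within 500 bp.

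Peaks at promoters were stronger than peaks elsewhere. The median signal was 179 over the 2217 TSS-proximal peaks and 132 over the other 363, a difference of 46.4. In the single lists the medians were 105 and 72.3 for replicate 1, and 94.8 and 77.3 for replicate 2. The two-sided permutation p was 1e-05, the smallest that 100000 resamples can give. Among peaks at an IDR of at most 0.001 the difference was 27.7 and did not pass, with a permutation p of 0.147.

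The strongest peak lay 49 bp upstream of the start of Ube3a, which encodes a ubiquitin ligase, at 3L 11210444 to 11210867 in dm6, with a signal of 1797 in the conservative list, 836 in replicate 1 and 963 in replicate 2. The next lay in an intron of org-1, a T-box transcription factor gene, at X 8452189 to 8452543, with a signal of 1365 (717 and 653 in replicates 1 and 2). It was the only one of the 25 strongest peaks outside a promoter. Promoters of Rpn6, a proteasome lid subunit (1129), milt, a mitochondrial transport adaptor (1104), and MESK2 (1078) followed. Also among the 25 were the promoters of RpL32, a ribosomal protein gene (961), Capr (945), hts, which encodes an adducin (893), kug, an atypical cadherin gene (864), and Daxx (820). CycB, which encodes a mitotic cyclin, had a signal of 740 and shtd, a subunit gene of the anaphase-promoting complex, 734. The others were Creld, Fit2, RhoGAP93B, EndoGI, CtsF, CG15443, CG8613, CG8547, Ccdc85, CkIIalpha-i1, CG9135, Scsalpha1 and jagn, with signals from 736 (jagn) to 978 (Creld). Each of the 25 had a ranked peak in both single lists.

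The tagged gene itself carried more conservative peaks than any other protein-coding gene. On tna (FBgn0026160, 3L 10835528 to 10876496, plus strand, 41.0 kb) 14 summits spread over 31.3 kb, 9 of them in introns and 1 within 500 bp of a start. The strongest lay in the 3′ UTR at 3L 10876139 to 10876318, with a signal of 491 in the conservative list, 235 in replicate 1 and 210 in replicate 2. The peak at an internal start, with its summit at 10857910, had a signal of 260 (86.6 and 167 in replicates 1 and 2). The replicate 1 list held 10 peaks on the gene and the replicate 2 list 13. With 1 peak per replicate pair there were 12 peaks on tna. At an IDR of at most 0.001 there were 3 peaks, and 6 had a q-value of at most 0.05.

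**Figure D2:**
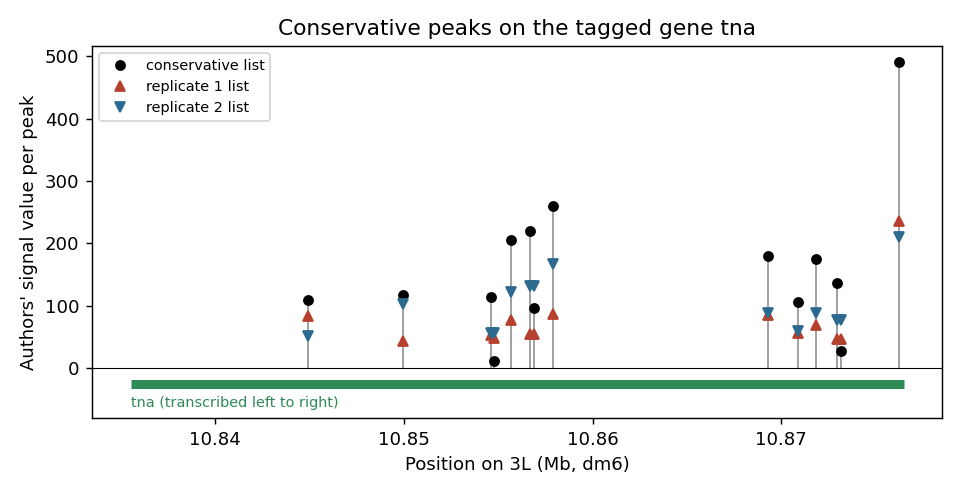
Authors' signal per peak against position on 3L (Mb) for the 14 conservative peaks on tna, with the highest overlapping ranked peak of each replicate as triangles and the gene as a green bar. The highest point, at a signal of 491, stands in the 3′ UTR at the right end of the gene.

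After tna, EcR, the ecdysone receptor gene, held 7 peaks over 81.2 kb, and Roc2 and mam, a Notch coactivator gene, held 6 each. ATP8A, Ptp61F, shn, a zinc-finger gene of Dpp signalling, and bin3 held 5 each, and foi and Sik3 held 4 each, named before other genes with 4 peaks for their higher summed signal. At least 3 peaks were found on 90 protein-coding genes.

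Of 13968 protein-coding genes, 2541 (18.2%) had a summit within 500 bp of a TSS. A gene with more annotated starts had more chances of such a summit, and the list tests did not match genes for their number of starts. Genes of cytosolic ribosomal proteins were bound more often than other genes, 37 of 86 (43.0%, 95% interval 32.4 to 54.2), with an odds ratio of 3.44 and an adjusted Fisher p of 6.93e-07. RpL32 (961), RpS2 (554), RpS30 (475) and RpS7 (404) had the highest signals among them. Insulator protein genes were bound at 7 of 13, an odds ratio of 5.20 (95% interval 1.82 to 14.9) and an adjusted Fisher p of 0.0191. They included BEAF-32 (243) and pita (278, a peak nearer the start of Dcp-1), and a peak of signal 192 lay near both Ibf1 and Ibf2. Ecdysone response genes were bound at 7 of 15, an odds ratio of 3.98 (95% interval 1.49 to 10.6) and an adjusted Fisher p of 0.0408, led by the nuclear receptor genes ftz-f1 (299), svp (264), usp (200) and EcR (181).

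With 1 gene per shared promoter neither list passed, though the odds ratios stayed about as large, 4.62 for insulator genes (adjusted Fisher p = 0.0576) and 4.18 for ecdysone genes (adjusted Fisher p = 0.0513). At an IDR of at most 0.001 they were 4.67 (adjusted Fisher p = 0.0830) and 1.82 (adjusted Fisher p = 0.704), and in single lists the ecdysone odds ratio was 2.66 in replicate 1 (adjusted Fisher p = 0.135) and 3.20 in replicate 2 (adjusted Fisher p = 0.0984). Ecdysone genes did not pass with a TSS window of 1000 bp (3.43, adjusted Fisher p = 0.0554) or with peak intervals over a TSS (3.09, adjusted Fisher p = 0.140) either.

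Genes of odorant, gustatory and ionotropic chemoreceptors were bound less often, 2 of 179 (1.12%) with an odds ratio of 0.0624 and an adjusted Fisher p of 5.11e-12. The 2 counted were Ir31a (132) and Ir60e (112), and both peaks lay nearer the start of another gene, LSm-4 and CG13585. Replication-dependent histone genes were bound at 0 of 111, which allows up to 3.27% by the exact interval, with an adjusted Fisher p of 3.90e-09. These genes are near-identical copies whose reads can be shared, so their value is uncertain, and 1 ranked peak near His2B:CG33868 was left out of the conservative list.

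Trithorax group and Brahma complex genes were bound at 9 of 23 (39.1%), an odds ratio of 2.95 that did not pass with an adjusted Fisher p of 0.0677. The highest signals among them were at kis (346) and fs(1)h (343), the latter nearer the start of mys. This list passed in each single list, with adjusted Fisher p-values of 0.00836 in replicate 1 and 0.0474 in replicate 2. It also passed with 1 gene per shared promoter (odds ratio 5.47, adjusted Fisher p = 0.00309) and at an IDR of at most 0.001 (odds ratio 4.49, adjusted Fisher p = 0.0232). The Trithorax list did not pass in the other list from both (2.74, adjusted Fisher p = 0.0509) or at an IDR of at most 0.05 (2.25, adjusted Fisher p = 0.111). Nor did it pass with a TSS window of 250 bp (2.90, adjusted Fisher p = 0.0504) or 1 peak per replicate pair (2.96, adjusted Fisher p = 0.0674). Polycomb group genes were bound at 8 of 20 (40.0%), an odds ratio of 3.06 with an adjusted Fisher p of 0.0594, and Scm (327) and Asx (260) led. The Polycomb list passed in 4 of 13 alternatives, among them a TSS window of 250 bp (adjusted Fisher p = 0.0268). The 13 include an IDR of at most 0.01, which returned the conservative list itself. The Polycomb list did not pass in replicate 1 (2.83, adjusted Fisher p = 0.0823) or replicate 2 (2.09, adjusted Fisher p = 0.310). Nor did it pass in the other list from both (2.39, adjusted Fisher p = 0.118) or at an IDR of at most 0.001 (1.97, adjusted Fisher p = 0.570). With the 88 ranked peaks on the arms that the conservative list left out added back, both lists passed, each with an adjusted Fisher p of 0.0166. SUMO pathway genes were bound at 4 of 10, with an adjusted Fisher p of 0.192. Among them the gene of the modifier itself, Sumo, had a promoter peak of signal 589, and a peak of 309 within 500 bp of dgrn lay nearer the start of Sec20.

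No other list passed in the conservative list. Proteasome subunit genes were bound at 14 of 48, led by Rpn6 (1129) and Prosalpha7 (707), and mitochondrial ribosomal protein genes at 18 of 73, led by mRpL4 (693) and mRpL30 (689). Cell cycle genes were bound at 7 of 22, with CycB (740) and CycA (260), and germline genes at 4 of 14, with tej (429) and tud (253). Segmentation genes were bound at 6 of 22, with odd (187) and opa (153), and Notch pathway genes at 4 of 19, with mam (256) and Su(H) (224). Among tissue markers the counts were 1 of 20 for neural genes (SoxN, 88.8), 3 of 20 for muscle (Mef2, 183, and Tm1, 158, nearer the start of MRG15) and 1 of 15 for hemocyte and fat body (ush, 195). Of the Hox genes 1 of 8 was bound (abd-A, 269), and of heat shock genes 2 of 17 (DnaJ-1, 427, and Hsp83, 235, nearer the start of CG14965). The adjusted Fisher p-values of these 11 lists ran from 0.141 for the proteasome to 1. In the other list made from both replicates, neural genes passed as bound less often, 0 of 20 (odds ratio 0.0855, adjusted Fisher p = 0.0390), and mitochondrial ribosomal protein genes as bound more often (odds ratio 1.85, adjusted Fisher p = 0.0438). Neural genes were also at 0 of 20 in each single list without passing, and with a TSS window of 250 bp the proteasome list passed (odds ratio 2.23, adjusted Fisher p = 0.0468).

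**Figure D3:**
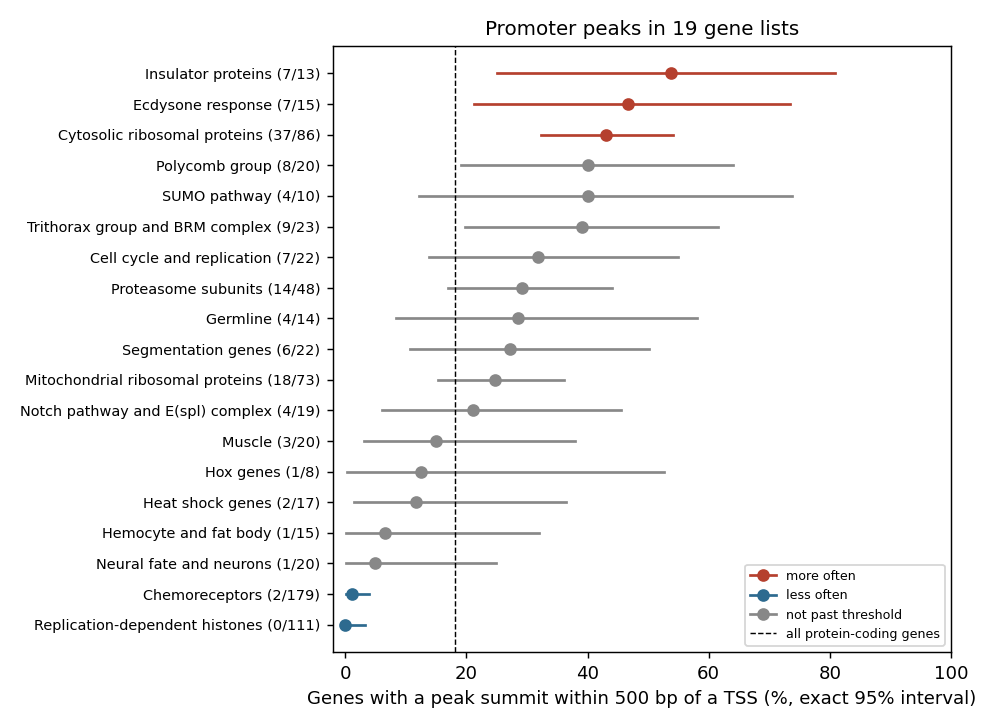
Percentage of genes in each of 19 lists with a summit within 500 bp of a TSS, as points with exact 95% intervals, and the value of all protein-coding genes as a dashed line. Colours mark the lists past the threshold, with ribosomal protein, insulator and ecdysone genes above the 18.2% line and chemoreceptor and histone genes near 0. Grey lists did not pass, though several, among them Trithorax, Polycomb and SUMO genes, also have their points above the line.

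The share of windows with a match differed most between summits and controls for CGATA, which the boundary protein BEAF-32 binds, and for the DNA replication-related element (DRE) that contains it. The DRE, TATCGATA, occurred within 100 bp of 603 summits (23.4%) and in 10 control windows (0.388%), with an adjusted exact McNemar p of 1.03e-162. CGATA occurred at 1677 summits (65.0%) against 526 control windows (20.4%), with an adjusted exact p of 1.35e-213. Motif 1, GGTCACAC, bound by M1BP, occurred at 147 summits (5.70%) against 21 control windows (0.814%), with an adjusted exact p of 3.20e-25. With the small constant added to each count, the ratio was 57.5 for the DRE and 6.86 for Motif 1, and in the replicate 2 list alone 25.2 and 16.7. DRE matches lay a median of 27 bp from the summit, and peaks with a DRE had a median signal of 216 against 156 for those without.

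The GAGA string (ratio 1.57), the Pho site (1.88), the Initiator (1.25) and the E-boxes CACGTG (1.61) and CAGCTG (1.27) were also more frequent at summits. In the replicate 1 list alone the GAGA string (1.04), Pho (1.69), the Initiator (1.05) and CACGTG (1.34) did not pass, with adjusted exact p-values from 0.104 for Pho to 0.975 for the GAGA string. CACGTG did not pass in replicate 2 either (1.30, adjusted exact p = 0.118), where the GAGA string had a ratio of 2.13. Sites for Zelda (ratio 0.475), Tramtrack (0.253) and GATA factors (0.688) were less frequent, but in replicate 1 alone Zelda (0.491, adjusted exact p = 0.0989) and GATA (0.761, adjusted exact p = 0.125) did not pass.

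Against promoters without a peak at the same offset, the ratio of the DRE was 12.6, of CGATA 2.56 and of Motif 1 1.63, and all 3 passed. The Initiator (0.716, adjusted exact p = 5.18e-09) and the TATA box (0.601, adjusted exact p = 4.70e-10) were on the lower side, and GATA sites stayed lower (0.435, adjusted exact p = 1.55e-09). The GAGA string (0.864), Pho (1.07), CACGTG (1.26), CAGCTG (1.19), Zelda (0.442) and Tramtrack (0.512) did not pass there, with adjusted exact p-values from 0.0638 for CAGCTG to 1 for Pho. Against the windows 1000 bp away, strings for CTCF, Su(Hw), the TATA box, AP-1, heat shock elements, CA repeats and homeodomain sites did not pass. The homeodomain string passed in each single list in opposite directions, at 1.27 in replicate 1 (adjusted exact p = 0.0204) and 0.790 in replicate 2 (adjusted exact p = 0.0154). Against dinucleotide-shuffled windows CA repeats (4.39, adjusted exact p = 4.21e-14) and the TATA box (1.31, adjusted exact p = 0.00420) passed, and the ratios of the GAGA string (3.16) and CAGCTG (3.90) were larger. Pho (1.23), CACGTG (0.990) and GATA sites (1.03) did not pass there, with adjusted exact p-values from 0.514 for Pho to 1 for CACGTG.

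**Figure D4:**
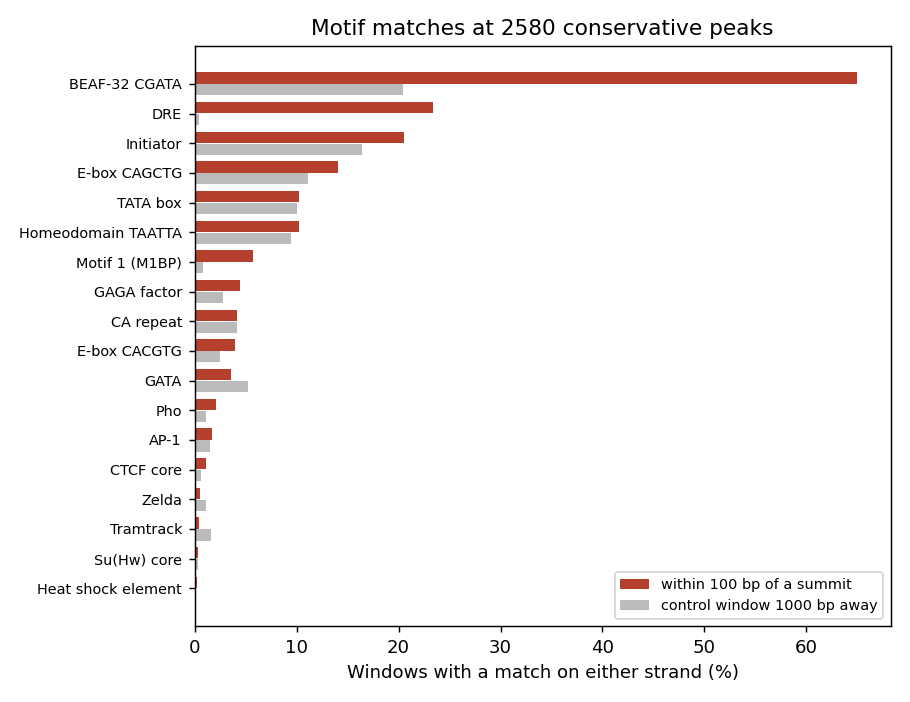
Percentage of windows with a match to each of 18 motifs within 100 bp of a summit (red) and in control windows 1000 bp away (grey). CGATA at 65.0% against 20.4% and the DRE at 23.4% against 0.388% differ most.

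Arm 2R held 577 peaks, 1.21 times its share of assembled bases, with an adjusted exact binomial p of 1.95e-06. Arm 4 held 13 peaks (ratio 0.519, adjusted exact p = 0.0275) and Y held 0 of 2580, which allows a share of up to 0.116% by the limit of 3 counts. Arm 4 did not pass in replicate 2 alone (0.772, adjusted exact p = 0.440), with 1 peak per replicate pair (0.556, adjusted exact p = 0.0663) or at an IDR of at most 0.001 (0.374, adjusted exact p = 0.0602). The 2L, 3L, 3R and X arms did not pass. X passed as higher in replicate 1 alone (1.10, adjusted exact p = 0.0453) and at an IDR of at most 0.001 (1.18, adjusted exact p = 0.0124), and as lower at an IDR of at most 0.05 (0.822, adjusted exact p = 3.15e-08). Arm 3L passed as lower at an IDR of at most 0.001 (0.841, adjusted exact p = 0.0124) and at a q-value of at most 0.05 (0.895, adjusted exact p = 0.0407). Against each arm's share of protein-coding TSSs no arm passed, and 2R had a ratio of 1.09 with an adjusted exact p of 0.117. By that share Y would hold 0.119% of peaks, and its count of 0 had an adjusted exact binomial p of 0.292.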

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

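The tests of the tna locus were chosen after its peaks were seen, while the bound of the planned comparison with promoters without a peak and the minimum of 10 genes in the test of shared tRNA reads were set after their results were seen.

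The ranked list of replicate pairs held 2673 peaks at an IDR of at most 0.01, of which the conservative list left out 93. The other thresholded lists left out such peaks too. These were 67 of 2284 in replicate 1, 122 of 2791 in replicate 2 and 124 of 3624 in the other list from both. Of the 93, 88 lay on the arms, 52 of them on 3R and 22 on 2L, and 67 of the 88 (76.1%) were TSS-proximal. Their median signal was 182, against 169 for the kept peaks. Among the 60 protein-coding genes bound only with left-out peaks, osa (845), a subunit gene of the Brahma complex, kibra (740) and rump (591) had the highest signals. They were named after their values were seen. Added back, osa and corto took the Trithorax and Polycomb lists past the threshold, each with an adjusted Fisher p of 0.0166. The left-out peaks stood in 48 runs without a kept peak between them, the longest of 8 peaks across tara on 3R. Mostly repeated sequence, by 31-mers, was found in 2 of the 88 (2.27%) and in 8 of the 2580 kept peaks (0.310%).

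The 14 peaks on the tagged gene tna are a pattern of the locus as a whole. With 1 peak per replicate pair there were 12, and the peaks per kb below were not recomputed that way. Gene length as the whole cause is argued against, since tna lay at the 99.9th percentile of peaks per kb among 1020 genes of at least 20 kb, with 0.342 peaks per kb against at most 0.208 (ATP8A) elsewhere, counting summits in the gene body without the 500 bp around it. Extra copies of the region in the tagged line may raise weak peaks too, and the lower quartile of ranked-peak signal over the gene was 1.34 times that of the 50 kb flanks in replicate 1 (permutation p = 0.0209) and 2.52 times in replicate 2 (permutation p = 1e-04, the smallest that 10000 resamples can give). The bound set for that explanation was 1.5 in each replicate, which replicate 1 did not reach. Binding across the gene would raise the lower quartile as well, so meeting the bound could not have separated the explanations. Extra copies therefore cannot be told apart from binding at the gene, and no control library was analysed here. The permutations also treated neighbouring peaks of 1 locus as independent.

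The DRE and CGATA show the largest differences in share between summits and control windows. Base composition of the windows is argued against by ratios over dinucleotide-shuffled copies of 63.5 for the DRE and 2.04 for CGATA, the latter down from 3.19, and a general property of promoters by ratios of 12.6 and 2.56 over promoters without a peak. Recovery of any strongly transcribed promoter, whatever protein is tagged, was examined within the ribosomal protein genes. There 34 of 56 promoters with CGATA near a start had a peak and 3 of 30 without it, an odds ratio of 12.05 (Fisher p = 3.63e-06). With only the most upstream start of each gene, a check added after seeing the result, it was 19.01. Transcription was not measured here, so ribosomal protein promoters with and without CGATA may differ in activity, as may promoters without a peak. Recovery of strongly transcribed promoters therefore cannot be told apart from binding, and open chromatin at DRE promoters stays untested.

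Genes of tRNAs carried peaks more often than protein-coding genes, 159 of 290 (54.8%) against 18.2%. Neighbouring protein-coding promoters as the whole cause are argued against, since tRNA genes with no protein-coding start within 1000 bp had an odds ratio of 4.80 (Fisher p = 1.80e-27), and 54 of 122 isolated clusters of tRNA genes (44.3%) had a peak. Reads shared between near-identical copies may contribute, and this cannot be told apart from binding, because only 3 tRNA genes had no 31-mer found elsewhere, under the minimum of 10. Of these 0 had a peak (odds ratio 0.642, Fisher p = 1), which met the bound first written for shared reads. No biological explanation was tested for these patterns, as the design has 1 group.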

How the results depend on the processing

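Alternatives at an IDR of 0.05 or 0.001, a q-value of 0.05, 1 peak per replicate pair and left-out peaks added back, and all those of the tna locus, were chosen after seeing the data. The IDR alternative of 0.01 returned the conservative list itself, so it could only repeat the main calls. It is still counted among the 12 alternatives of the TSS-proximal share, the 13 of gene lists and motifs and the 10 of arms. The TSS-proximal share passed in all 12 alternatives, from 70.5% to 94.3%, and the replicate overlap in 3, from 55.2% to 66.6%. Ribosomal protein and chemoreceptor genes, the DRE, CGATA and Motif 1 passed in all 13 of theirs, histone genes too, insulator genes in 11, ecdysone genes in 7, Trithorax genes in 8, Polycomb genes in 4, mitochondrial ribosomal and proteasome genes in 3 each, and neural genes in 1. In either direction and of 13 alternatives, Tramtrack sites passed in 12, the Initiator and CAGCTG in 10 each, GATA in 8, the GAGA string and TAATTA in 7 each, Pho in 6, Zelda and CACGTG in 5 each, the TATA box in 4 and CA repeats in 2. Of 10 alternatives for arms, 2R and Y passed in 9 each, arm 4 in 6, X in 4, 3L in 2 and 2L in 1. Where a value moved, the cause was not tested. At an IDR of 0.05 there were 4836 peaks, 5 arms and 8 lists past the threshold. At 0.001 there were 1100 peaks, 3 on tna, 5 motifs, and a signal difference of 27.7 that did not pass. At a q-value of 0.05 there were 1674 peaks, 6 on tna, 5 arms and 5 motifs. Single replicates gave 6 to 11 motifs, promoter-matched controls 6, and TSS shares 0 arms. The replicate r was 0.319 over all ranked pairs and 0.626 without the top 5%. Ratios on the other side of 1 from the main result, where either value passed, were counted as reversed. In the other series-wide list these were TATA 0.852 and TAATTA 0.839. In single lists they were TAATTA 0.790 in replicate 2 and arm X 1.10 in replicate 1. TAATTA in replicate 1 (1.27) and arm X in replicate 2 (0.906) kept the main direction. At an IDR of 0.05 TATA (0.793) and TAATTA (0.813) were reversed, and at 0.001 arm X (1.18) and GAGA (0.831). At a q-value of 0.05 it was arm X (1.12), and in windows reaching 50 bp TAATTA (0.705). Against shuffled windows CACGTG (0.990) and GATA (1.03) were reversed, and against promoters GAGA (0.864), TATA (0.601) and Initiator (0.716). The reversed GAGA, CACGTG and GATA values did not pass, and the other reversed values did. No paired analysis was possible because there is 1 group.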

Other observations

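The tests of tRNA peaks, of sequences and transposable elements away from starts and of random pairs of promoters were chosen after the results were seen. Of the 119 peaks within 500 bp of a tRNA start, 101 lay away from any protein-coding TSS. CGATA stood within 100 bp of 22 of the 119 summits (18.5%), against 67.2% of other peaks, with a Fisher p of 1.73e-26. Their median signal was 200 against 167. Most other peaks lay at protein-coding starts and were not split by location. The difference in CGATA therefore cannot be told apart from one between peaks at and away from such starts. Among other noncoding classes, not tested, 120 of 3289 ncRNA genes (3.65%), 19 of 269 snoRNA genes (7.06%), 5 of 32 snRNA genes (15.6%) and 0 of 99 rRNA genes had a peak. The exact 95% interval reaches 32.8% for snRNA genes, and rRNA genes are repeated copies whose reads can be shared.

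Peaks away from starts differed in sequence from those at starts. The DRE occurred at 27 of 363 such summits (7.44%) against 26.0%, an odds ratio of 0.233 (Fisher p = 2.68e-17), and the GAGA string at 29 (7.99%) against 3.88%, an odds ratio of 2.17 (Fisher p = 0.00135). Annotated transposable elements held 31 of these summits (8.54%) and 7 of the 2217 at starts (Fisher p = 6.22e-21). Starts of transposable elements were not among the TSSs, so a summit at such a start could count as away from starts. No share expected by position was computed either, so this difference cannot be told apart from one set by the definition.

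A hypothesis, written before its test, was that peaks favour divergent promoters, where starts of opposite strands lie within 500 bp. A summit lay within 250 bp of the start at 466 of 1736 divergent promoters (26.8%) and at 1101 of 10487 others (10.5%), an odds ratio of 3.13 (Fisher p = 1.69e-66), counting 1 start per divergent pair. A divergent promoter has 2 starts and so 2 chances of a peak, but random pairs of the other promoters had a peak at either start in a mean of 19.9% and at most 22.2% of 1000 draws (permutation p = 0.001, the smallest possible), so this is argued against as the whole cause. Divergent starts may still differ from others in other ways, such as the presence of the DRE, which was not tested.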
